A study of Homo sapiens with 4 samples.

How the data were processed

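Total RNA of THP-1 cells was extracted with a Qiagen RNeasy Plus Mini kit and made into libraries with NEBNext Ultra II, per the labels' protocols. The 4 samples form 2 groups by their labels, 2 with a non-targeting oligonucleotide and 2 with an oligonucleotide against SGOL1-AS1. STAR 2.5.1b, DESeq2 (no version given) and the genome build GRCh38 are named, with no role or order, per the submitters' processing notes. The annotation release, the counting tool and the strand setting are not given in the sources used here. The deposited values are a normalized signal per gene, read counts that the authors divided by 1 size factor per library. Whole reads were recovered from every value, the largest distance from a whole read being 0.000468. The recovered totals were 50855150 and 51851314 reads in the non-targeting and 48558537 and 41435922 in the knockdown libraries, and the most abundant gene, RN7SL1, took 3.19% to 3.78% of them.

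The table holds 27106 genes. Each has at least 2 reads in knockdown library 1, while 2375, 2132 and 2092 genes have fewer in knockdown library 2 and non-targeting libraries 1 and 2, so the table was filtered on that library and genes lost from it are not analysed here. The non-targeting columns carry the names of their samples. The other 2 columns carry a code that the labels do not explain and replicate numbers that differ in part from the labels. They were taken as the knockdown group by elimination, because they are not named non-targeting and the labels hold 1 other group, at the same day. They are numbered here in column order and are not paired with the non-targeting libraries. Counts of the 2 non-targeting libraries differed by a chi-square of 4.94 per degree of freedom and those of the 2 knockdown libraries by 5.49, against 9.5 to 13.5 between groups, so no library was a copy of another. Gene symbols came from a table of Ensembl identifiers, with 26579 matched, and positions and gene types from GENCODE 29 on GRCh38, with 26077 matched.

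Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), over 19398 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Log2 fold changes are knockdown minus non-targeting. Of 33 gene lists fixed before the data were examined, the 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, and 18 were past the threshold with the preset and 0 with the estimate. With the estimate camera also takes its degrees of freedom from the 4 libraries, which leaves few. A call lost there is therefore no measure of correlation between genes alone. Lists with an estimate under the preset lost their calls too, such as lysosome and autophagy (-0.018) and JAK-STAT signalling (-0.007). Within each list, p-values were also adjusted over the list alone. The genes named were, by a rule fixed before the data were examined, SGO1-AS1 and SGO1, the 6 largest rises and 6 largest falls among called genes with a symbol, a mean of at least 50 and both knockdown values on the same side of both non-targeting values, up to 3 members with the smallest p of each list past the threshold and of the inflammatory, cell death, p53, G2/M and monocyte lists, and the neighbours of the target. The rule took 75 genes, some of which are not reported here, and genes outside it are marked as named after their values were seen.

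Alternatives were no filter or a minimum mean of 50, pseudocounts of 0.5 and 5, 3 other scalings, robust empirical Bayes, no trend, each library left out in turn, other thresholds, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and, chosen after seeing the data, a correction of each library for GC content and exonic length. With 1 library left out, the lone sample of its group is assumed to vary like the other group. The biological coefficient of variation by edgeR was 4.47%. The tests were checked on simulated counts for 19404 genes with the real means and library sizes: limma recovered 74 of 99 genes changed 1.5-fold (74.7%) and 82 of 97 changed 2-fold (84.5%), and 9 of its 165 calls (5.45%) were false. Camera called 1 of 31 lists in the same simulated counts, where the changed genes were drawn at random and not by list. Each simulated gene took its dispersion from the trend with the mean alone, much as limma's trend setting assumes. The false share holds for that case and is not an error rate of the calls in the real data. The simulated genes varied independently of each other. The simulation therefore does not check camera where genes of a list vary together, as in the interferon-stimulated list, with an estimated correlation of 0.726. Intervals on read counts are exact Poisson intervals at 95% and cover counting error only.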

Results

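Gene expression was measured by RNA sequencing of total RNA from THP-1 cells, a human acute myeloid leukaemia line of monocytic type that carries the MLL-AF9 fusion. The cells had received an antisense oligonucleotide, a short synthetic nucleic acid that pairs with an RNA and lowers it. It was either non-targeting (2 libraries) or directed against the long noncoding RNA SGOL1-AS1 (2 libraries), and the libraries are labelled day 5. The libraries held 50855150 and 51851314 gene reads in the non-targeting group and 48558537 and 41435922 in the knockdown group. The title of the series names cell survival in leukaemia and pro-inflammatory signalling as its subject, so the gene lists for these 2 themes are described first. The labels do not say that the libraries came from separate cultures, and the p-values then measure only the spread between these samples, which may be technical.

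The targeted RNA, SGO1-AS1 (the current symbol of SGOL1-AS1; ENSG00000231304), lies on the plus strand of chromosome 3 from 20174244 to 21145967 (GRCh38). It had 24 and 21 reads in the non-targeting libraries and 12 and 17 in the knockdown libraries. The normalized count was 21.4 ± 2.33 (SD, n = 2) against 15.4 ± 5.57, a log2 fold change of -0.48 ± 0.37 (SE) that did not pass the threshold (limma, adjusted p = 0.555). The pooled read rate in the knockdown was 0.735 times that in the non-targeting libraries, with an exact 95% Poisson interval of 0.445 to 1.2 that covers counting error only. A loss of the target was therefore not detectable at this depth, and its level does not check the labels. The knockdown libraries were assigned to their group by elimination, since their columns carry a code that the labels do not explain, and every direction given here rests on that assignment. Both columns carry the same code, and no other oligonucleotide against the target is labelled. Effects of losing the target therefore cannot be told apart from other effects of this oligonucleotide. SGO1, the cohesin protector that overlaps it on the minus strand (20160593 to 20186292), was at 1747 ± 28.4 and 1790 ± 64.1 (limma, log2 fold change 0.03, adjusted p = 0.84). The sources used here do not say whether counting used strand, so reads in the shared stretch could belong to either gene. Of the 6 tested genes on the list of neighbours, none passed the threshold over all genes or adjusted over the list alone (camera, adjusted p = 0.887; adjusted p = 0.932 with an estimated correlation). They were SGO1, TBC1D5, SATB1, RAB5A, KAT2B and ZNF385D, with log2 fold changes from -0.08 to 0.16.

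**Figure D1:**
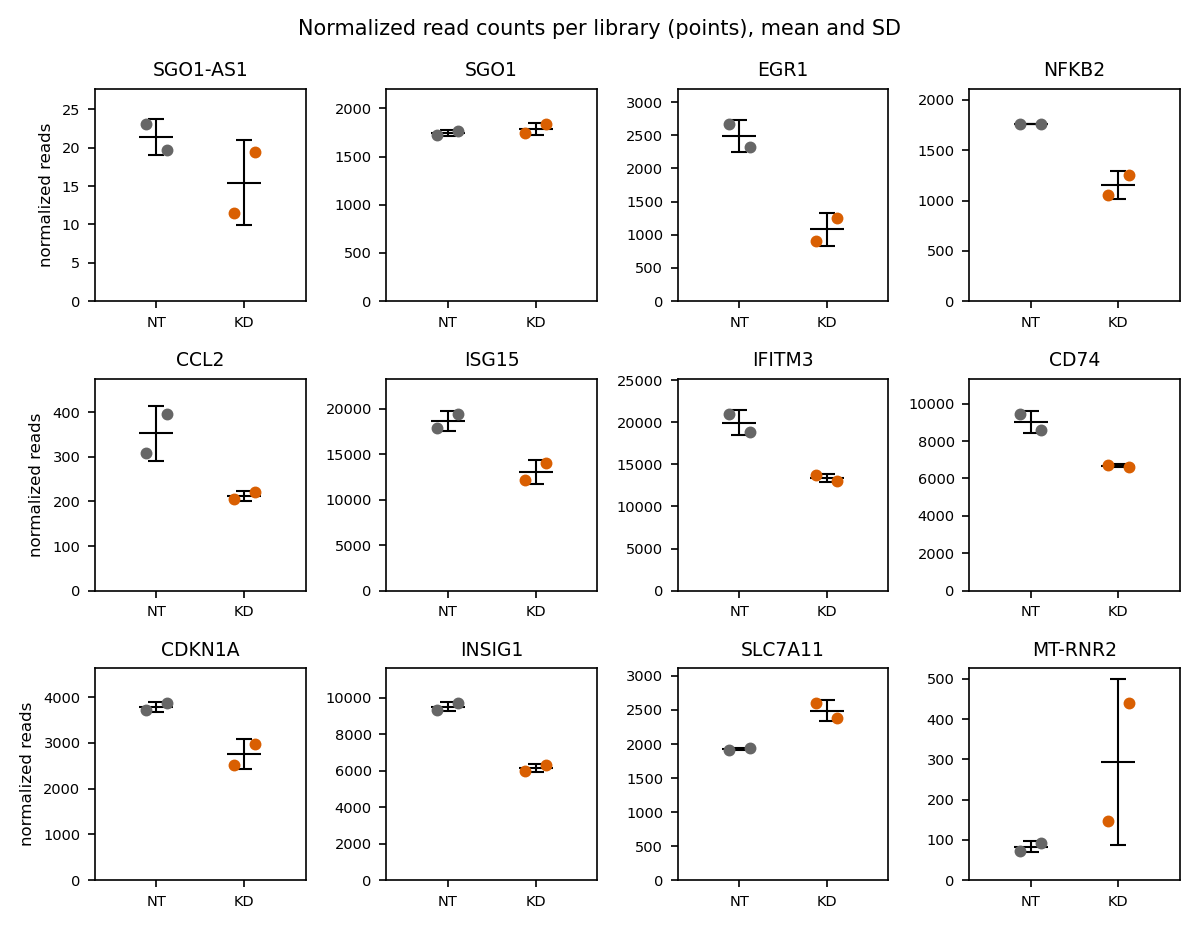
Normalized read counts (linear axes from 0) of 12 genes in the 2 non-targeting (NT, grey) and 2 knockdown (KD, orange) libraries. Points are libraries, the horizontal bar is the mean and the whiskers are 1 SD. EGR1 stands at 2494 ± 241 in NT and 1083 ± 250 in KD while the SGO1-AS1 ranges lie close together.

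Most of the genes that changed were lower in the knockdown. Of 19398 genes tested, 660 fell and 165 rose (limma, adjusted p under 0.05), with median log2 fold changes of -0.32 and 0.38. Genes with fewer than 2 reads in knockdown library 1 are not analysed here, so the count of lower genes leaves out any that were lost from it. The changes were modest: 84 of the lower and 33 of the higher genes reached a fold of 1.5, and 15 and 11 reached a fold of 2. Protein-coding genes made up 95.8% of the lower and 53.9% of the higher genes, against 68.5% of all tested genes. Higher and lower genes differed in this share (Fisher's exact test, two-sided, p = 1.32e-37 across genes, which are not independent). In all 825 called genes both knockdown values lay on the same side of both non-targeting values, as they did in 46.7% of all tested genes, where chance gives 33.3%. The share of calls that were lower, 80%, was 69.1% with the same median in every library, 70.2% after quantile normalization and 55.5% with the same total in every library. Without non-targeting library 1 the counts were 334 lower and 87 higher, and the higher count was 90 without non-targeting library 2 and 309 without knockdown library 2. Limma with no mean-variance trend called 0 genes, with 2337 at an unadjusted p under 0.05, where edgeR called 556 lower and 159 higher and DESeq2 380 and 67.

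**Figure D2:**
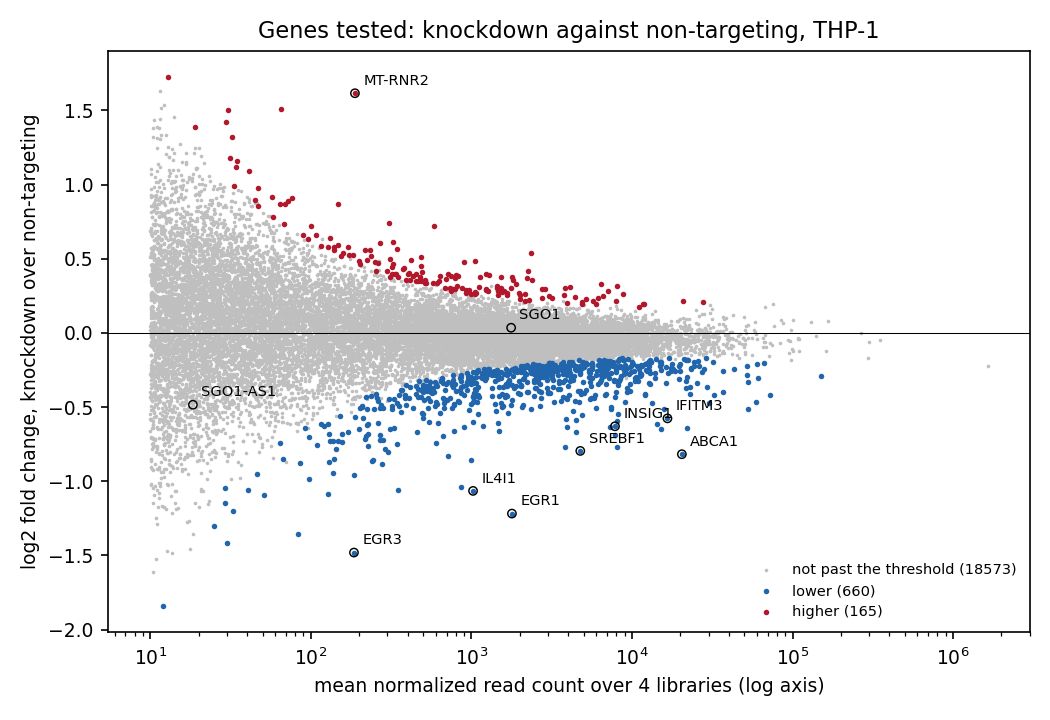
Log2 fold change of knockdown over non-targeting against the mean normalized read count of the 4 libraries (log axis) for the 19398 tested genes. Blue points are the 660 lower genes, red points the 165 higher genes and grey points the rest.

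Interferon-stimulated genes, which cells switch on in response to type I interferon, were lower as a group. Of the 34 tested, 33 fell over all genes and 34 adjusted over the list alone, with a median log2 fold change of -0.42 (camera, adjusted p = 4.42e-48). The call was lost when camera estimated the correlation from the data, which also leaves few degrees of freedom (adjusted p = 0.336 with an estimated correlation). ISG15, a ubiquitin-like antiviral protein, fell from 18641 ± 1120 to 13053 ± 1313 normalized reads (SD, n = 2; limma, log2 fold change -0.52 ± 0.06 SE, adjusted p = 1.2e-05). IFITM3, which blocks viral entry and shares sequence with its neighbours, fell by 0.58 on the log2 scale, and IFI35 fell by 0.55. The list's median lay further from the non-targeting mean in knockdown library 1, at -0.55, than in knockdown library 2, at -0.29, while the non-targeting libraries stood at -0.05 and 0.05. Of the 31 genes listed for the interferon-gamma response and antigen presentation 18 were tested, since 11 of the list's 18 genes in the MHC region and 2 others were not analysed here. Of these 18, 7 fell over all genes and 11 adjusted over the list alone (camera, adjusted p = 3.96e-11; adjusted p = 0.336 with an estimated correlation). CD74, the invariant chain of MHC class II, fell from 9022 ± 612 to 6683 ± 70.1 (limma, adjusted p = 3.06e-05). HLA-DRB1, a class II chain with close paralogs, fell by 0.39 on the log2 scale and the GTPase GBP4 by 0.50. The call of GBP4 ended with robust empirical Bayes (adjusted p = 0.0616).

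NF-kB target genes and immediate early genes also fell. Of 20 tested NF-kB targets, 9 fell over all genes and 13 adjusted over the list alone (median log2 fold change -0.25; camera, adjusted p = 1.6e-12; adjusted p = 0.220 with an estimated correlation). NFKB2, the precursor of p52, fell from 1757 to 1154 ± 135 normalized reads (limma, log2 fold change -0.61 ± 0.07 SE, adjusted p = 2.45e-05). Its partner RELB fell by 0.52 on the log2 scale and the IkB family member BCL3 by 0.78. Of 27 tested immediate early genes, which answer growth factor and stress signals within minutes, 16 fell over all genes and 18 adjusted over the list alone (median -0.32; camera, adjusted p = 7.08e-17; adjusted p = 0.220 with an estimated correlation). EGR3 fell furthest, from 270.0 ± 9.3 to 101.2 ± 45.5 (limma, log2 fold change -1.48 ± 0.20 SE, adjusted p = 6.84e-05). EGR1 fell by 1.22 and the AP-1 subunit JUNB by 0.44. The EGR1 and EGR3 calls ended with robust empirical Bayes (adjusted p = 0.174 and 0.122), with the same fold changes.

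Of 26 inflammatory cytokines and chemokines 14 were tested and 12 were not analysed here. Among the 14, 5 fell over all genes and 6 adjusted over the list alone (median -0.27; camera, adjusted p = 0.000194; adjusted p = 0.341 with an estimated correlation). CCL2, a monocyte chemoattractant, fell from 352.6 ± 61.4 to 212.2 ± 11.2 (limma, log2 fold change -0.72 ± 0.13 SE, adjusted p = 0.00111), and the macrophage growth factor CSF1 fell by 0.54 on the log2 scale. TNFSF10, the death ligand TRAIL, fell by 0.43, and LIF and CXCL8, named after their values were seen, fell by 0.95 and 0.33. In Toll-like receptor signalling 4 of 23 genes fell over all genes and 5 adjusted over the list alone (camera, adjusted p = 0.00736; adjusted p = 0.336 with an estimated correlation). These were UNC93B1, which carries endosomal receptors, by 0.41, the adaptor MYD88 by 0.30, IRF7 by 0.73 and IRF5, named after its value was seen, by 0.19. In JAK-STAT signalling 6 of 23 fell over all genes and 9 adjusted over the list alone (camera, adjusted p = 6.86e-06; adjusted p = 0.220 with an estimated correlation). The kinase PIM3 fell by 0.33 and STAT2 by 0.32. In the inflammasome and interleukin-1 pathway 2 of 16 fell, over all genes and adjusted over the list alone (camera, adjusted p = 0.0378; adjusted p = 0.354 with an estimated correlation). The inflammasome adaptor PYCARD fell by 0.31 and the interleukin-1 antagonist IL1RN by 0.36, while TXNIP was at -0.17 (adjusted p = 0.128). Of 12 complement and Fc receptor genes 2 fell over all genes and 4 adjusted over the list alone (camera, adjusted p = 0.00307; adjusted p = 0.433 with an estimated correlation). FCGR1A, which has close paralogs, fell by 0.37 and C3AR1 by 0.53. Without non-targeting library 2 the calls of MYD88 (adjusted p = 0.082), C3AR1 (0.0515), the complement list (0.0649) and the inflammasome list (0.186) ended, and without non-targeting library 1 that of IRF7 (0.251). Without knockdown library 1 the complement list (0.0675), the inflammasome list (0.258) and TNFSF10 (-0.25, adjusted p = 0.0614) lost theirs, and IL1RN stood at -0.23 and STAT2 at -0.20. The inflammasome list also lost its call with a minimum mean of 50 (0.134), quantile normalization (0.163), the same total (0.0975), no trend (0.155) and edgeR (0.0542). Quantile normalization ended the call of TNFSF10 (0.0509) and DESeq2 that of IRF7 (0.054), and TXNIP was called lower without knockdown library 2 (-0.29, adjusted p = 1.98e-05) and after the GC correction (0.0455).

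**Figure D3:**
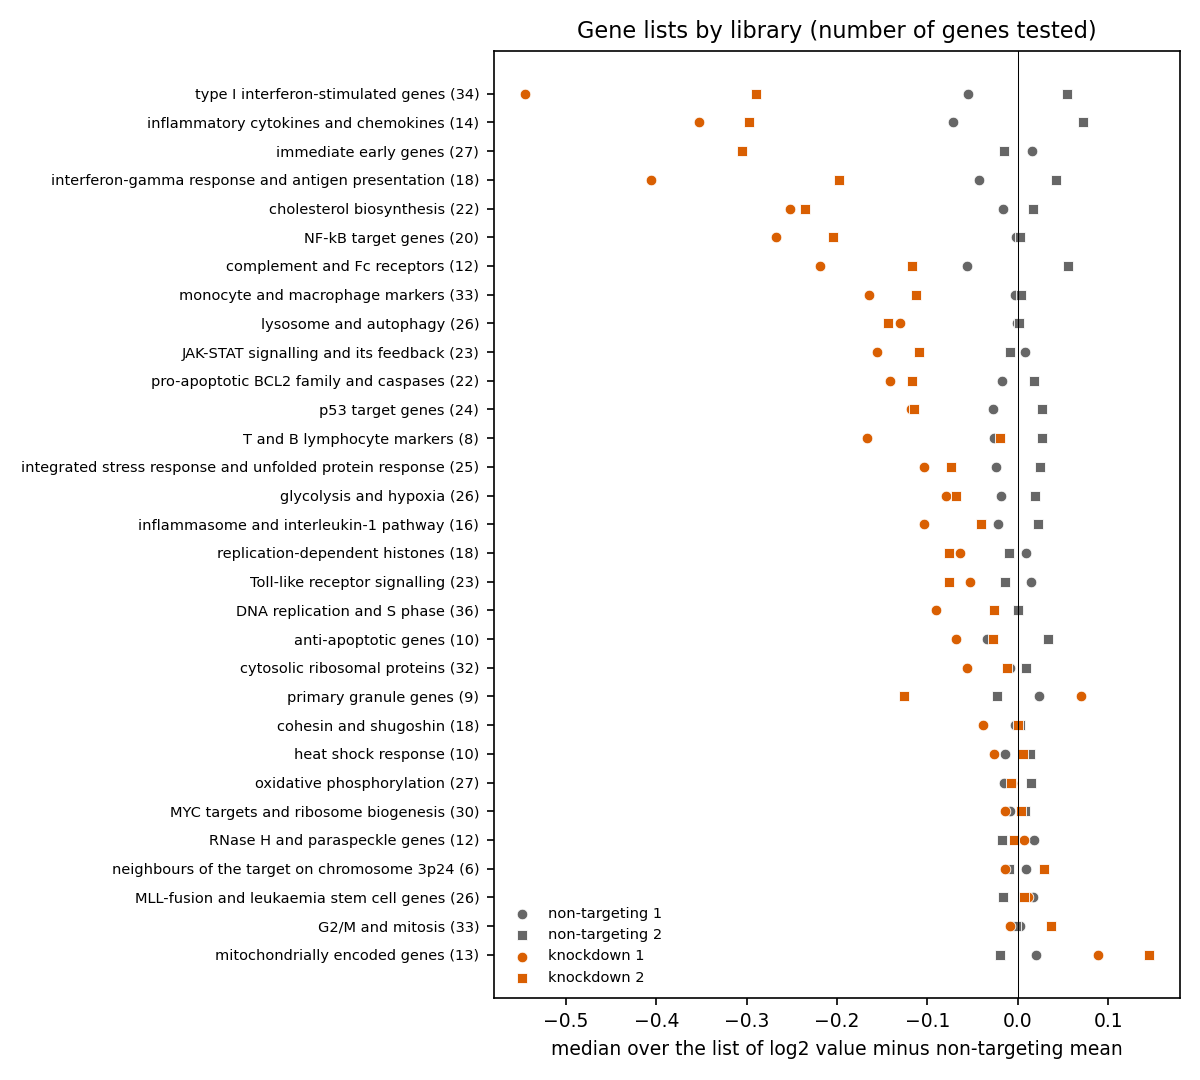
Median over each gene list of the log2 normalized count minus the non-targeting mean (horizontal axis, log2 units) for each of the 4 libraries, with the number of genes tested in parentheses. Grey marks are non-targeting and orange marks knockdown libraries, circles library 1 and squares library 2, and type I interferon-stimulated genes stand at -0.55 and -0.29 in the knockdown libraries while immediate early genes stand at -0.30 in both.

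Some pro-apoptotic genes and p53 targets fell, while none on the G2/M, cohesin or DNA replication lists passed the threshold by limma. Over all genes, 660 of 19398 tested fell. Of 22 tested pro-apoptotic genes 3 fell over all genes and 4 adjusted over the list alone (median -0.14; camera, adjusted p = 6.86e-05; adjusted p = 0.341 with an estimated correlation). Among them PMAIP1, the BH3-only protein NOXA, fell by 0.32 on the log2 scale and the TRAIL receptor TNFRSF10B fell by 0.31. Of 10 anti-apoptotic genes 0 passed over all genes by limma and 1 fell adjusted over the list alone (camera, adjusted p = 0.215; adjusted p = 0.745 with an estimated correlation). MCL1 was at -0.17 (adjusted p = 0.0814), BIRC3 at -0.25 and XIAP at -0.11. Of 24 p53 target genes 4 fell over all genes and 7 adjusted over the list alone (camera, adjusted p = 0.000264; adjusted p = 0.341 with an estimated correlation). CDKN1A, a cell cycle inhibitor, fell from 3791 ± 106 to 2754 ± 325 (limma, log2 fold change -0.47 ± 0.07 SE, adjusted p = 0.000142) and BTG2 by 0.40. None of 33 G2/M and mitosis genes passed over all genes or adjusted over the list alone (median 0.01; camera, adjusted p = 0.444; adjusted p = 0.803 with an estimated correlation). BUB1B and CENPE were at 0.13 and BUB3 at -0.11. None of 18 cohesin and shugoshin genes passed either (camera, adjusted p = 0.482; adjusted p = 0.792 with an estimated correlation). The 36 DNA replication genes were shifted down as a list (median -0.06; camera, adjusted p = 0.016; adjusted p = 0.493 with an estimated correlation). By limma 0 of them passed over all genes or adjusted over the list alone, with MCM2 at -0.14 and POLA1 at 0.14. The G2/M list was called higher after quantile normalization (0.0082) and with the same total (0.0257). The replication list lost its call in 8 of 15 alternatives, with adjusted p up to 0.575, among them without non-targeting library 2 (0.146) and without knockdown library 1 (0.258). The call of TNFRSF10B ended without non-targeting library 1 (0.0816), non-targeting library 2 (0.123) or knockdown library 1 (-0.17, adjusted p = 0.29), and that of PMAIP1 without non-targeting library 2 (0.215). Quantile normalization and the same total also ended the calls of TNFRSF10B (0.122 and 0.121) and PMAIP1 (0.0636 and 0.0672), and edgeR (0.0512) and DESeq2 (0.121) that of TNFRSF10B. MCL1 was called lower with robust empirical Bayes (0.0402), without knockdown library 2 (-0.25, adjusted p = 0.000252) and after the GC correction (0.0251), and POLA1 higher with the same total (0.0371).

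Monocyte markers moved both ways. Of 33 tested, 6 fell and 3 rose over all genes, and 10 fell and 4 rose adjusted over the list alone (median -0.12; camera, adjusted p = 0.016; adjusted p = 0.433 with an estimated correlation). CD4 fell from 6911 ± 3.59 to 5440 ± 102 (limma, log2 fold change -0.35 ± 0.05 SE, adjusted p = 0.000193). The calprotectin subunits S100A8 and S100A9 and the proteoglycan VCAN, named after their values were seen, rose by 0.38, 0.30 and 0.33 on the log2 scale. S100A8 stood at 2234 and 1833 normalized reads in knockdown libraries 1 and 2, from a non-targeting mean of 1558. S100A9 stood at 4566 and 3947, from 3437, and VCAN at 6654 and 7613, from 5657. Of 26 MLL-fusion and leukaemia stem cell genes, MEIS1, a HOXA9 cofactor, rose by 0.41 (limma, adjusted p = 0.00241) and 0 fell, with 2 higher adjusted over the list alone (camera, adjusted p = 0.321; adjusted p = 0.711 with an estimated correlation). MEIS1 stood at 2878 and 2276 normalized reads in knockdown libraries 1 and 2, from a non-targeting mean of 1920. None of 9 primary granule genes passed over all genes, and 2 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.972; adjusted p = 0.979 with an estimated correlation). Of 8 T and B lymphocyte markers the B-lineage factor PAX5, named after its value was seen, fell by 0.58, over all genes and adjusted over the list alone (camera, adjusted p = 0.263; adjusted p = 0.473 with an estimated correlation). None of the 3 erythroid and megakaryocyte or 4 epithelial and fibroblast markers tested passed by limma over all genes or adjusted over the list alone, too few for camera. The monocyte list lost its call with a minimum mean of 50 (0.134) and after correction for GC content and exonic length (0.095). The MLL-fusion list was called higher without knockdown library 2 (0.0261) and after quantile normalization (0.0276), and the lymphocyte list was called lower without non-targeting library 1 (0.0423) or knockdown library 2 (0.033).

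Cholesterol synthesis genes fell. Of 22 tested, 14 fell over all genes and 17 adjusted over the list alone (median -0.26; camera, adjusted p = 3.45e-17; adjusted p = 0.220 with an estimated correlation). INSIG1, which retains the sterol-sensing machinery in the endoplasmic reticulum, fell from 9524 ± 250.1 to 6156 ± 235 (limma, log2 fold change -0.63 ± 0.05 SE, adjusted p = 1.02e-07). The sterol carrier STARD4 fell by 0.36 on the log2 scale. Of 26 lysosome and autophagy genes 4 fell over all genes and 11 adjusted over the list alone (camera, adjusted p = 1.5e-06; adjusted p = 0.220 with an estimated correlation). The cathepsins CTSS and CTSZ fell by 0.32 and 0.28. Of 26 glycolysis and hypoxia genes 3 fell over all genes and 5 adjusted over the list alone (camera, adjusted p = 0.000194; adjusted p = 0.354 with an estimated correlation). The angiogenic factor VEGFA fell by 0.37 and the enzymes PGAM1 and PFKP by 0.27 each. In the integrated stress and unfolded protein responses 5 of 25 fell and 1 rose over all genes, and 7 fell and 1 rose adjusted over the list alone (camera, adjusted p = 0.00174; adjusted p = 0.433 with an estimated correlation). SLC7A11, the cystine transporter, was the member that rose, from 1929 ± 18.4 to 2490.3 ± 150.9 (limma, log2 fold change 0.37 ± 0.06 SE, adjusted p = 0.000885), and EDEM1 fell by 0.26. Without non-targeting library 2 the calls of the stress list (0.113) and EDEM1 (0.152) ended, and the stress list also lost its call without knockdown library 1 (0.0511) and after quantile normalization (0.0558).

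Mitochondrially encoded mRNAs were the only one of the 31 lists tested that camera called higher at its preset correlation. Of 13 tested, MT-CO3 and MT-ND6 rose over all genes, by 0.21 and 0.31 on the log2 scale, and 6 rose adjusted over the list alone (median 0.12; camera, adjusted p = 6.42e-07; adjusted p = 0.341 with an estimated correlation). None of 27 nuclear-encoded oxidative phosphorylation genes passed over all genes by limma or adjusted over the list alone (camera, adjusted p = 0.887; adjusted p = 0.938 with an estimated correlation), where the list's median was -0.01 and camera's direction was up. Of 32 cytosolic ribosomal protein genes RPL11 rose by 0.22 (camera, adjusted p = 0.323; adjusted p = 0.792 with an estimated correlation). Of 18 replication-dependent histone genes H2BC5 rose by 0.23 (camera, adjusted p = 0.0865; adjusted p = 0.354 with an estimated correlation), and of 12 RNase H and paraspeckle genes the noncoding RNA NEAT1 rose by 0.20 (camera, adjusted p = 0.172; adjusted p = 0.433 with an estimated correlation). These 3 genes were named after their values were seen, and each list had 1 gene higher adjusted over the list alone, beside 4 histone genes that were lower. Of 30 MYC target and ribosome biogenesis genes RRP12 and TFRC, named after their values were seen, fell by 0.20 and 0.19, 2 over all genes and 2 adjusted over the list alone (camera, adjusted p = 0.863; adjusted p = 0.916 with an estimated correlation). None of 10 heat shock genes passed over all genes or adjusted over the list alone (camera, adjusted p = 0.863; adjusted p = 0.916 with an estimated correlation). Correction for GC content and exonic length, chosen after seeing the data, ended the calls of the mitochondrial list (0.111), MT-CO3 (0.0821) and MT-ND6 (0.226) and made the histone list lower (0.00192), as did testing without a filter (0.0227). The paraspeckle list was called higher after quantile normalization (0.00274) and with the same total (0.0181). Quantile normalization also turned the ribosomal protein (0.0207) and MYC target (0.0307) lists to called higher. The MT-CO3 call also ended without non-targeting library 1 (0.118), non-targeting library 2 (0.215) or knockdown library 2 (0.052). MT-ND6, which stood at 0.52 without knockdown library 1, lost its call without non-targeting library 2 (0.0583) or knockdown library 2 (0.10, adjusted p = 0.364), with a minimum mean of 50 (0.0645), with robust empirical Bayes (0.595) and with DESeq2 (0.572).

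The largest rises among genes with a mean of at least 50 were the mitochondrial rRNAs MT-RNR2, from 83.1 ± 14.3 to 293.4 ± 206.1 normalized reads (limma, log2 fold change 1.62 ± 0.28 SE, adjusted p = 0.00109), and MT-RNR1, from 30.4 ± 3.13 to 99.3 ± 64.4 (1.51 ± 0.31, adjusted p = 0.00502). They were followed by the noncoding RNA LINC01117 at 0.92, the pseudogene MMADHCP2 and ANKS1B at 0.87 each and the pseudogene PEX12P1 at 0.74. Reads of pseudogenes and mitochondrial genes can be shared with near-identical copies. The largest falls, beside EGR3 and EGR1, were the autotaxin gene ENPP2 at -1.35, the lysosomal protease LGMN at -1.09, the semaphorin receptor NRP2 at -1.09 and the amino acid oxidase IL4I1, from 1382 ± 123.8 to 666 ± 142 (limma, -1.07 ± 0.10 SE, adjusted p = 8.71e-07). Without knockdown library 2 MT-RNR2 stood at 0.83 and MT-RNR1 at 0.80 (adjusted p = 0.153), and robust empirical Bayes ended both calls (0.471 and 0.196), as did DESeq2 for MT-RNR2 (0.214). Without knockdown library 1 PEX12P1 stood at 0.44, NRP2 at -0.72 and MMADHCP2 lost its call (0.14), which also ended without non-targeting library 1 (0.263). The calls of LINC01117 (0.141) and LGMN (0.144) ended without non-targeting library 2, those of LINC01117 (0.0526) and MMADHCP2 (0.0706) after quantile normalization, and that of MMADHCP2 after the GC correction (0.0562).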

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

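The GC content and exonic length correction was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the columns of the 2 groups share only 1 replicate number, so the planned replicate block was not run, and camera has no robust setting. None of the 825 called genes reversed direction in the filters, pseudocounts, scalings, empirical Bayes settings, left-out libraries, edgeR or DESeq2. Only the scalings, edgeR and DESeq2 could have reversed them. Filters and empirical Bayes settings do not alter a fold change. Both knockdown values of every called gene lay on the same side of both non-targeting values, which fixes the direction under a pseudocount or a left-out library. The 165 higher genes became 290 with the same median, 67 with DESeq2, 46 at an adjusted p under 0.01, 33 at a fold of 1.5 and 344 at an adjusted p under 0.1, and the 660 lower genes became 334 after quantile normalization, 293 with the same total, 380 with DESeq2, 337 at an adjusted p under 0.01 and 84 at a fold of 1.5. With no trend both counts were 0. Leaving out 1 library gave 87 to 309 higher and 334 to 960 lower genes. The thresholds are stricter or looser by construction, DESeq2 left 6770 genes without an adjusted p, and for the others the cause was not tested. The number of lists past the threshold, 18, lay between 14 and 20, and was 0 with an estimated correlation, where 2 libraries per group leave few degrees of freedom. 12 of the 18 lists kept their call in all 15 other alternatives. Of the 56 named genes that were called, 43 to 56 kept their call in each alternative other than no trend, which kept 0, and DESeq2 (47 of 51 with an adjusted p). SGO1-AS1 stayed short of the threshold in every alternative that tested it, from -0.13 to -0.84 with 1 library left out. The results that reversed were not past the threshold to begin with. After quantile normalization these were SATB1 (0.0375) and the adjusted p of the lists for cohesin (0.355), MYC targets (0.0307), primary granules (0.841), heat shock (0.0938) and ribosomal proteins (0.0207). The MYC target and ribosomal protein lists were past the threshold there, as higher. With the same total they were SATB1 (0.0227), cohesin (0.593), MYC targets (0.257), primary granules (0.912), heat shock (0.477) and ribosomal proteins (0.511), and with the same median MYC targets (0.918) and primary granules (0.894). A minimum mean of 50 reversed MYC targets (0.905), primary granules (0.935) and heat shock (0.935), no filter oxidative phosphorylation (0.909), no trend oxidative phosphorylation (0.949), edgeR primary granules (0.985), DESeq2 heat shock (0.843) and the GC correction MYC targets (0.347) and the neighbours of the target (0.733). Leaving out 1 library reversed, over ranges given here for all 4 such fits, SATB1 (-0.071 to 0.0020), SGO1 (-0.0018 to 0.0712) and the lists for G2/M (0.112 to 0.976), the neighbours (0.729 to 0.976), cohesin (0.303 to 0.969), ribosomal proteins (0.132 to 0.969), MYC targets (0.688 to 0.9746), primary granules (0.564 to 0.869) and oxidative phosphorylation (0.563 to 0.92). The cause was not tested. Depth limits the target, with 12 to 24 reads per library.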

Other observations

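Genes named in this part were chosen for the text after their values were seen. SREBF1, the lipogenic transcription factor, fell from 6051 ± 462.9 to 3481 ± 146.1 normalized reads (SD, n = 2; limma, log2 fold change -0.80, adjusted p = 5.74e-08). The fatty acid synthase FASN fell by 0.52 on the log2 scale, the desaturases SCD, FADS1 and FADS2 fell by 0.47, 0.47 and 0.60, and the synthesis and elongation genes ACACA (-0.05, adjusted p = 0.953) and ELOVL5 (-0.06, adjusted p = 0.628) did not pass the threshold. ABCA1, the cholesterol exporter, fell by 0.82 and the lipid carrier APOE by 0.76. The receptor tyrosine kinases RET and AXL fell by 0.64 and 0.65, the matrix protease inhibitor TIMP3 by 0.77 and the lectin CD209 by 0.77. CD209 stood at 2237 and 3500 normalized reads in knockdown libraries 1 and 2, from a non-targeting mean of 4779. The exonuclease ISG20 fell by 1.04, the chemokine CXCL10 by 0.96 and the inhibitory receptor LAG3 by 0.94. Among genes that rose were MS4A3, a marker of granulocyte-monocyte progenitors, by 0.38, the cyclin CCND2 by 0.28 and the noncoding RNA EPIC1 by 0.72.

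The fall of ABCA1 and SREBF1, both targets of the sterol receptor LXR, raised the hypothesis of lower LXR activity, tested on 22 other LXR targets listed before the value of any of them was seen. Their median log2 fold change was -0.226 (camera, adjusted p = 1.71e-11 over 32 lists), which is consistent with the hypothesis. By limma 9 fell and 0 rose over all genes, and 13 fell adjusted over the list alone. The call was lost when camera took the correlation from the data, again with few degrees of freedom (adjusted p = 0.325 with an estimated correlation). Without FASN, SCD, FADS1, FADS2 and APOE, left out after their values were seen, 4 of the other 17 fell over all genes and 8 adjusted over the list alone, and the median was -0.14 (camera, adjusted p = 0.000286; adjusted p = 0.425 with an estimated correlation). Several of the 9, such as FASN, SCD and FADS2, are also targets of SREBF1 itself, and SMPDL3A, APOC1 and PLTP also fell, by 0.51, 0.37 and 0.24 on the log2 scale. ABCG1 (-0.27, adjusted p = 0.0529), MYLIP (-0.18, adjusted p = 0.122) and LPCAT3 (-0.21, adjusted p = 0.0864) passed only adjusted over the list alone, and MERTK, at 0.08, passed neither. No test here separates LXR from SREBF1.

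Technical explanations were weighed for 3 patterns. The tests of all mitochondrial RNA and of sense intronic genes and all 3 tests of the distance between the knockdown libraries were chosen after their results were seen, and the others before. Long noncoding RNAs made up 32.7% of the higher and 1.52% of the lower genes, against 17.5% of all tested genes. Pseudogenes made up 8.48% of the higher and 0.455% of the lower genes, against 9.31% of all tested genes. Pseudogenes were therefore in no excess among the higher genes, and both classes were scarce among the lower genes. After correction for GC content and exonic length 86.1% of the higher genes stayed called, so that trend does not account for most of these calls. The coding share of all genes called higher was then 65.3% (245 genes), against 53.9% before and 68.5% of all tested genes. Much of the noncoding excess was therefore absent from the corrected calls, and a GC content and length trend as its cause stays open. The lower genes were still 92.3% coding. More unspliced RNA in the knockdown remains a candidate explanation: over the 12651 coding genes not called lower the fold change rose with the ratio of genomic span to exonic length (Spearman 0.133 across genes, above the mark of 0.1 set beforehand, and 0.136 over all 13283 tested coding genes), although the correlation in knockdown library 1 (-0.02) was no higher than in non-targeting library 2 (-0.02), and those of non-targeting library 1 and knockdown library 2 were -0.16 and 0.19. The median of 386 sense intronic genes, relative to the mean of the 4 libraries, was -0.12 and -0.10 in the non-targeting and 0.18 and 0.06 in the knockdown libraries, and the median ratio of span to exonic length was 10.3 in the higher and 5.22 in the lower coding genes. Reads from genomic DNA cannot be told apart from no such reads, because the rate on 23 silent genes was 1.14 times the non-targeting rate in knockdown library 2 (exact 95% interval 0.994 to 1.30) and 1.34 times in knockdown library 1 (1.19 to 1.52), where the filter of the table on that library can raise it, and a biological rise stays open.

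Mitochondrial rRNA rose most, from a very small share of the reads. The 2 rRNAs took 0.000216% and 0.000249% of reads in the non-targeting libraries and 0.000432% and 0.00124% in the knockdown libraries. MT-RNR2 had 76 to 385 reads per library, where the mitochondrial mRNA MT-CO3 had 26883 to 29973. More mitochondrial RNA of every kind as the whole cause is argued against, since the 2 rRNAs lay 1.45 log2 units above the median of the 13 mRNAs, by 0.73 in knockdown library 1 and 2.16 in knockdown library 2, against -0.06 and 0.06 in the non-targeting libraries. Less complete removal of rRNA cannot be told apart from other causes. Reads on 37 5S rRNA genes and pseudogenes were 1.36 times as frequent in knockdown library 2 as in the non-targeting libraries (exact 95% interval 1.15 to 1.6). That ratio is below the 1.5 times set beforehand, a mark that was written for nuclear-encoded rRNA genes. In knockdown library 1 the ratio was 1.54 (1.32 to 1.8), but the filter of the table can raise it there, so the 2 ratios cannot be compared. Genes typed as nuclear rRNA took 1.38e-05% and 9.64e-06% of reads in the non-targeting and 8.24e-06% and 0% in the knockdown libraries. These reads were too few for a test. They were also far fewer than the 198 to 293 reads per library on the 5S set. Most of the 5S reads therefore lay on entries not typed as rRNA, and their ratio cannot decide whether rRNA was removed less completely. MT-RNR2 stood 0.83 and 2.40 log2 units above the non-targeting mean in the 2 knockdown libraries, and a biological rise stays open.

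Knockdown library 1 moved further than knockdown library 2, with medians of -0.36 and -0.30 over the lower genes and 0.43 and 0.33 over the higher genes. It lay further from the non-targeting mean in 74.5% of the higher and 68.9% of the lower genes, which argues against a scaling offset, since that would push the 2 directions apart. Within genes, interferon-stimulated genes were 0.28 log2 units lower in knockdown library 1 (33 of 34 genes), immediate early genes 0.0456 (quartiles -0.06 to 0.18) and cholesterol synthesis genes 0.0482 (quartiles -0.04 to 0.09), while the list medians in knockdown libraries 1 and 2 were -0.41 and -0.20 for the interferon-gamma response, -0.12 in both for p53 targets, -0.13 and -0.14 for lysosome genes and -0.05 and -0.08 for Toll-like receptor signalling. Fewer affected cells in library 2, which could act on every list, cannot be told apart from a difference in interferon response. The quartiles over the immediate early genes, -0.06 to 0.18, allow no gap as well as a clear gap. The lysosome and Toll-like receptor medians lay lower in library 2, the other way. The 2 non-targeting libraries themselves differed by 0.11 over the interferon-stimulated genes (31 of 34 genes), so that list can also differ without a knockdown. Less loss of the target in library 2 cannot be told apart either, because its read rate there was 1.66 times that in library 1 (exact 95% interval 0.747 to 3.81, p = 0.195).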
